A study of Arabidopsis thaliana with 9 samples.

How the data were processed

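DNA methylation was measured by MethylC-seq, whole-genome sequencing of bisulfite-treated DNA, in roots of Arabidopsis thaliana seedlings grown for 6 days at 22 °C with 16 hours of light and 8 hours of darkness, per the labels' protocols. Cells were released from lines that mark a cell type with green fluorescent protein and sorted by fluorescence. The 9 libraries form 7 groups: epidermis, cortex, endodermis from 2 lines, stele, columella root cap, lower columella, and whole root tips of the Col-0 wild type and of PET111, the enhancer trap line from which the columella root cap cells were sorted. The endodermis lines and the root tips were treated as the replicates of their groups. The labels do not say whether the endodermis libraries came from separate plantings, so p-values rest on the spread between these libraries, which may be technical. The root tips also differ in line and in read depth, so their spread is not that of like replicates.

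The deposited files hold counts: for each listed cytosine the number of methylated reads and the number of all reads covering it, with its position, strand and context (CG, CHG or CHH, where H is A, C or T). Coordinates are on TAIR10, per the submitters' processing notes. The aligner, the caller and its error rate are not given in the sources used here. In all 9 files no listed site had 0 methylated reads, so the files list the cytosines called methylated and leave out covered, unmethylated ones. The files cover chromosomes 1 to 5. A level over all covered cytosines, and a correction for incomplete conversion from the chloroplast, cannot be computed from them, and the number of called sites grows with read depth. Epidermis and endodermis line 1 stand apart in processing: at CG sites with 20 reads their lowest number of methylated reads was 3, against 2 in the other 7 libraries, and their highest coverage was 84 and 83 reads, against 100 or 101. At CHH sites with 20 reads the lowest number was 4 in the PET111 root tip and 3 in every other library.

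The plan fixed before the data were examined foresaw such files. Called cytosines with at least 3 reads were counted per library, per 1 kb tile, per protein-coding gene body and per gene flank, in each context. Counts were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) over 7 groups, with the logarithm of each library's number of called CG sites as offset. Regions needed 10 called sites summed over the libraries. A region was called when the Benjamini-Hochberg adjusted p was under 0.05 and the change was at least 2-fold. The minimum difference in level that the plan named needs unmethylated sites, so the 2-fold minimum took its place. It and the minimum of 10 called sites were set after the files had been opened and before any region was tested. The model has 2 residual degrees of freedom, from the endodermis lines and the root tips, and each lone library is assumed to vary like these. The contrasts compared each columella population with the equal-weight mean of epidermis, cortex, endodermis and stele, the columella populations with each other, each of the 4 other tissues with the remaining 3, and the columella root cap with the root tips, 8 contrasts in all.

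Library totals and levels of the 2 columella libraries were compared with the 5 other sorted libraries by a two-sided exact permutation test. Its 21 splits cannot give a p under 0.0952. Values of these 6 tests were adjusted together. Levels are the methylated share of reads over sites listed with 3 reads in all 9 libraries, which are sites methylated in every library and not the genome average. Wilson 95% intervals cover counting error only. Median coverage of listed sites was 21 reads in epidermis, 22 in cortex, 19 and 22 in endodermis lines 1 and 2, 24 in stele, 25 in columella root cap, 16 in lower columella, 17 in the Col-0 root tip and 7 in the PET111 root tip.

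To set libraries of unequal depth side by side, depth-matched counts were added after the data had been seen. Each site with at least 10 reads was thinned to 10 reads, and the expected number of sites with at least 4 methylated reads among them was divided by the share of common CG sites (listed in at least 6 of the 8 other libraries) that reached 10 reads. That share was 82.5% to 87.9% in 8 libraries and 18.4% in the PET111 root tip. Other added alternatives were limma 3.58.1 on log2(sites + 1), leaving out epidermis and endodermis line 1, and depth-matched sites without the PET111 root tip. Alternatives chosen before the data were examined were site minimums of 1, 5 and 10 reads, equal offsets, TMM factors, tiles and flanks of 500 bp, no minimum change, leaving out regions above 3 times the median coverage, the root tip as reference, and leaving out each replicate.

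Gene names came from a RefSeq gene table of the TAIR10.1 assembly, which gives no strand and no transposons. It was used for names and for which genes lie at a called site, and none of its coordinates are printed. Because the upstream side of a gene is unknown without strand, the planned promoters were replaced by flanks of 1 kb on both sides of each of 27444 protein-coding genes. Planned transposon comparisons and CHH trinucleotide classes were not run. Positions given for a gene are its first and last called cytosine. Pericentromeres were the stretches of low gene density in 100 kb bins, 17 Mb in all.

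Named genes followed a rule fixed before the data were examined. It names the genes that drive the reporters, up to 4 examples of each of 10 gene lists (fewer, or none, where a list had few members with CHH calls), the 10 flanks with the largest CHH change called in each columella contrast, up to 5 gene bodies with the largest called CG gain and loss, and up to 3 called regions per direction of the other contrasts. The library had to lie beyond all 5 other sorted libraries, or all libraries of its reference. Of 109 list entries, 7 were left out because the gene table gives their locus another name or none, which leaves 100 different genes.

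The tile test was tested on simulated counts drawn around the observed means. In columella root cap 100 tiles were changed 4-fold and 100 changed 8-fold, raised and lowered by turns. The test was run on the contrast of columella root cap with the other tissues only. For CG (65419 tiles) it recovered 75 of the 4-fold and 91 of the 8-fold tiles, with 2 false calls. For CHH (33718 tiles) at the observed dispersion of 0.328 it recovered 2 of the 4-fold and 21 of the 8-fold tiles, with 0 false calls. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.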

Results

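The study profiled DNA methylation in 6 sorted cell populations of the Arabidopsis root meristem and in whole root tips, to see how methylation differs between root cell types. Epidermis cells were sorted by a WER reporter, cortex by an AT1G09750 reporter, endodermis by a SCR reporter in 2 lines, stele by a WOL reporter, lower columella by a CYCD5 reporter and columella root cap by the PET111 enhancer trap. Epidermis, cortex, stele and both columella populations have 1 library each. The files listed between 2566407 methylated cytosines (PET111 root tip) and 5984412 (columella root cap). Coverage summed over listed cytosines was 164005364 in columella root cap, 81557390 in lower columella, 68994280 to 97481478 in the 5 other sorted libraries, 64380127 in the Col-0 root tip and 18895569 in the PET111 root tip. A read counts once for each listed cytosine it covers, so these sums grow with the number of listed sites and are not numbers of reads. No pair of libraries held the same values: at sites listed in both, methylated and total reads were both equal at 0.363% to 1.49% of sites.

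Both columella populations carried far more methylated CHH cytosines than any other sorted population. Columella root cap had 3329285 called CHH sites and lower columella 2519331, against 1235100 ± 169400 (SD, n = 5) in epidermis, cortex, endodermis and stele, which is 2.70-fold and 2.04-fold. The 5 other libraries ranged from 1065312 in endodermis line 1 to 1430056 in endodermis line 2, so the endodermis lines themselves differed 1.34-fold. By depth-matched sites, which need at least 4 methylated reads among 10, the gain was 4.48-fold in columella root cap and 2.91-fold in lower columella. The endodermis lines then differed 1.13-fold. Equal depth and the demand for 4 methylated reads were not told apart as sources of the larger fold. Scaled by coverage of CHH instead of CG sites, columella root cap had 1557782 and lower columella 1147860 depth-matched CHH sites. The other sorted libraries then had 374515 (stele) to 458703 (endodermis line 1). Sites methylated in every library were also methylated more fully. At 174565 shared CHH sites the level was 60.4% in columella root cap (Wilson 95% interval 60.4 to 60.5), 50.7% in lower columella (50.6 to 50.7), and 40.6% ± 2.18 (SD, n = 5) in the other sorted libraries, whose highest was 42.9% in endodermis line 1. The root tips had 38.9% (Col-0) and 46.6% (PET111). The exact permutation test gave p = 0.0952 for the number of sites (log2 ratio 1.24) and for the level (difference 15.0 percentage points), the smallest value 2 against 5 libraries allow, and 0.286 after adjustment over the 6 tests. Epidermis and endodermis line 1 had a stricter lower limit for CG calls. Without them the log2 ratio was 1.13 and the level difference 15.9 points, each with exact permutation p = 0.20, the smallest possible there. Those 2 libraries hold no columella cells. They also enter the epidermis and endodermis contrasts, and endodermis line 1 enters the spread behind the edgeR tests, so their stricter calls may bear on these too.

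The number of CG sites was nearly even across cell types, and CHG levels were highest in stele and the 2 columella populations. Columella root cap had 1560161 and lower columella 1623177 called CG sites, against 1598400 ± 21610 (SD, n = 5), a log2 ratio of -0.01 (exact permutation p = 0.857, adjusted 0.857). Under depth matching the log2 ratio was 0.01, so its sign depends on the count used. CG levels at 1240028 shared sites were 88.5% in columella root cap, 85.9% in lower columella and 88.4% in stele, and lowest in cortex with 80.2% (exact permutation p = 0.191, adjusted 0.286). Called CHG sites were 1.07-fold the other sorted libraries in the 2 columella libraries together (exact permutation p = 0.191, adjusted 0.286) and depth-matched CHG sites 1.27-fold in columella root cap and 1.13-fold in lower columella. CHG levels at 558160 shared sites ran from 52.4% in cortex and 53.5% in epidermis through 58.5% and 61.9% in the endodermis lines to 66.9% in stele, 66.6% in columella root cap and 63.6% in lower columella. The columella mean level lay 6.49 points above the other sorted libraries, whose SD was 6.01 (n = 5, exact permutation p = 0.286, adjusted 0.343). By depth-matched CHG sites columella root cap (864385) and lower columella (773927) lay above stele (763426) and the 4 remaining sorted libraries (exact permutation p = 0.0952, the smallest possible).

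**Figure D1:**
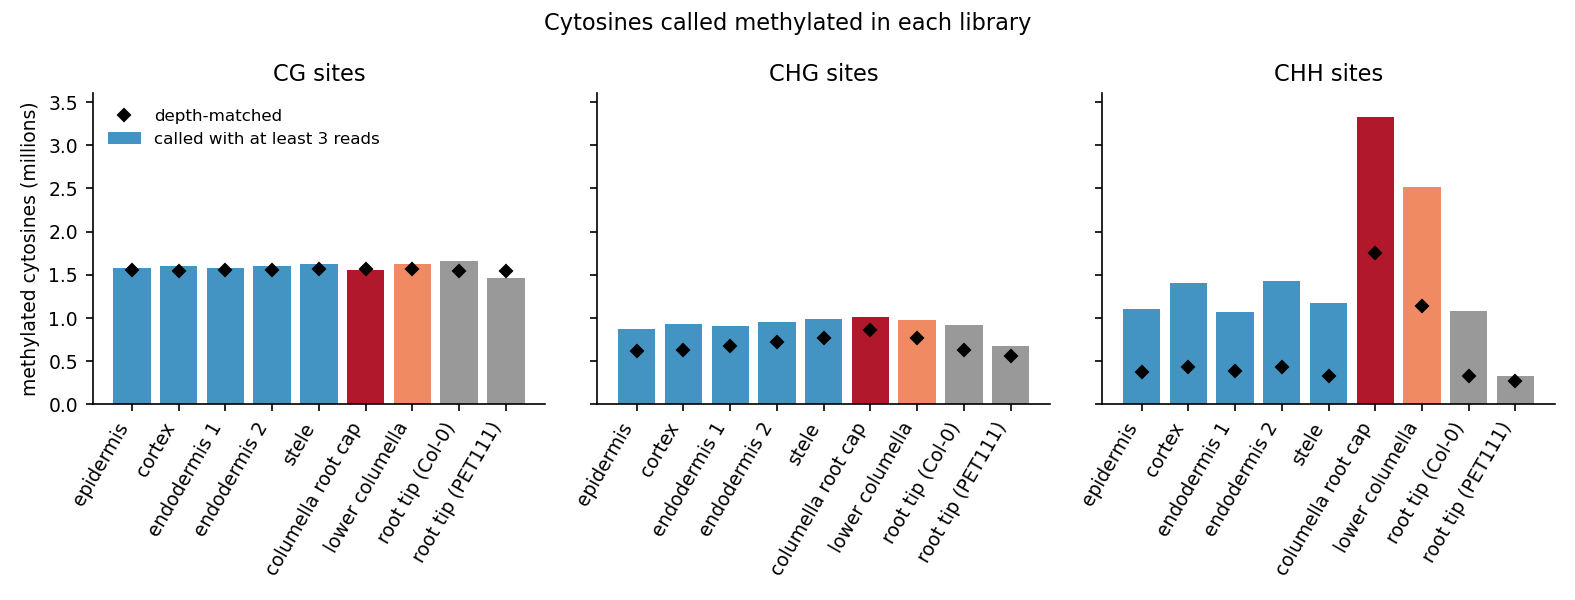
Called cytosines with at least 3 reads (bars) and depth-matched cytosines (diamonds) in each of the 9 libraries, by context. CG bars are nearly level, while the CHH bars of columella root cap (3329285) and lower columella (2519331) stand above the highest other sorted library (1430056).

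The CHH gain reached every class of region examined. With pseudogene loci set apart from the classes by distance to genes, the gain was largest more than 1 kb from protein-coding genes. In depth-matched sites it was 6.00-fold in columella root cap and 3.77-fold in lower columella more than 1 kb from protein-coding genes, 5.39-fold and 3.10-fold in the pericentromeres, 4.32-fold and 3.19-fold within 1 kb of a gene, and 4.25-fold and 2.77-fold inside gene bodies. Loci that the gene table types as pseudogenes gained least by this count, 3.21-fold and 1.92-fold. They held 49.44% of the called CHG sites of columella root cap and 49.61% of those of lower columella, and 30.55% and 27.57% of the called CHH sites. The gene table gives no transposons, so how many of these loci are transposon genes is not known. By called sites they gained least in lower columella (1.65-fold), while columella root cap gained least within 1 kb of a gene (2.35-fold, against 2.42-fold at pseudogenes). Folds by distance to genes with pseudogene loci counted in were not computed. The exact permutation test gave p = 0.0952 in each of the 6 classes, by called and by depth-matched sites, the smallest value possible, and 0.0952 after adjustment over these 12 tests, which cannot change equal values. Most of the extra calls lay on DNA that was already methylated. Of the 105820 tiles with a call in any library, 29008 held 5 or more CHH calls in the Col-0 root tip, and these held 95.2% of the CHH calls of columella root cap and 95.6% of those of lower columella, against 97.7% to 98.6% in the other sorted libraries. Each such tile held 109 CHH calls on average in columella root cap and 83.0 in lower columella, against 36.2 to 48.2. Another 27471 tiles had mainly CG methylation in the Col-0 root tip, as in methylated gene bodies: 5 or more CG calls and at most 1 CHG and 1 CHH call. The Col-0 root tip itself had 853 CHH calls there. These tiles held 0.588% and 0.472% of the columella CHH calls, against 0.203% to 0.317% in the other sorted libraries. Their calls were few but stood further above the other tissues in ratio than those of CHH-methylated tiles: 0.712 per tile in columella root cap and 0.433 in lower columella, against 0.0789 to 0.15. Tiles without any call in the Col-0 root tip held 8595 and 5616 CHH calls, against 2229 to 3735.

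**Figure D2:**
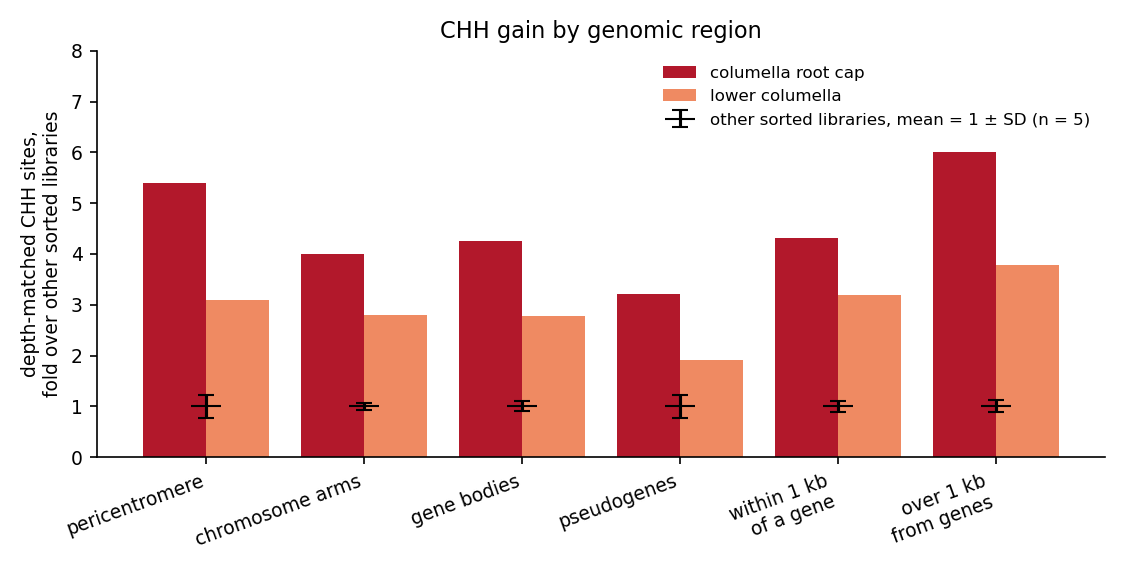
Depth-matched CHH sites in columella root cap and lower columella, as fold over the mean of the 5 other sorted libraries (y axis), by class of region. Black marks show those 5 libraries at 1 ± SD. The bars run from 1.92-fold (lower columella, pseudogenes) to 6.00-fold (columella root cap, over 1 kb from genes).

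Tile by tile, nearly the whole CHH-methylated genome was higher in the columella. In columella root cap 98.6% of 33718 tested CHH tiles lay above the mean of the other tissues, with a median log2 change of 1.45, and edgeR called 3411 tiles higher and 1 lower. In lower columella 95.4% lay above, with a median of 0.95, and 1060 tiles were called higher and 4 lower. The gains went together: 996 tiles were called higher in both, where independent lists of these sizes would share 107 (16295 against 14300 with depth-matched sites), and log2 changes correlated across tiles with r = 0.811 (tiles are not independent replicates). Both contrasts share their reference libraries, so part of the overlap would arise without a common gain, and how large a part was not computed for the lists. For the correlation, simulated unchanged libraries against that reference gave r = 0.167, and with separate reference libraries for each population the observed correlation was r = 0.769. The simulated libraries held no gain, so how far a gain alike across the genome would correlate is not known. Lower columella was not called different from columella root cap at any CHH tile by edgeR, with 199 tiles at an unadjusted p under 0.05, and limma called 114 higher and 448 lower. The median lay 0.47 below on the log2 scale, and 11.2% of tiles were higher in lower columella.

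The number of called CHH tiles depended strongly on which replicates set the spread, while the direction did not. Without endodermis line 1 or line 2, 0 tiles were called in either columella contrast (edgeR; 1891 and 2445 tiles had an unadjusted p under 0.05 for columella root cap, 986 and 1411 for lower columella), and 98.5% and 98.9% of tiles still lay above the other tissues in columella root cap. Without the Col-0 or the PET111 root tip, 18068 and 18150 tiles were called higher in columella root cap and 2492 and 2301 in lower columella. Among the libraries left when epidermis and endodermis line 1 were taken out, 0 tiles were called in either contrast, with 1026 and 494 at an unadjusted p under 0.05. TMM factors, which centre the tiles on their median, left 3838 tiles higher and 768 lower in columella root cap, and 3678 higher and 169 lower in lower columella, relative to that median.

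Near genes, the flanks with the largest CHH gains held few methylated CHH cytosines in the other tissues and many in both columella populations. Of 8705 gene flanks with CHH methylation, edgeR called 189 higher in columella root cap and 33 in lower columella, and 0 lower in either (1500 and 896 had an unadjusted p under 0.05; limma called 677 and 423 higher, 5 and 6 lower). The flanks of MRU1 (AT5G35490) held 422 methylated CHH cytosines in columella root cap and 385 in lower columella, against 8 to 45 in the other sorted libraries, 32 in the Col-0 and 3 in the PET111 root tip, with called sites from 13688821 to 13691546 on chromosome 5 (TAIR10). Its log2 change was 3.94 (SE 0.93, edgeR adjusted p = 0.00822) in columella root cap and 3.75 (SE 0.93, adjusted p = 0.0332) in lower columella. The flanks of AT5G35480, which share calls with those of MRU1, and of AT5G35475, beyond it, had 531 and 476 CHH calls in columella root cap against at most 105 and 75 in the other sorted libraries. AT2G11045 on chromosome 2 (calls from 4439647 to 4442543) had 404 and 352 in the columella populations against 19 to 55, with log2 changes of 3.75 and 3.50.

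The other flanks named for columella root cap were those of AT1G43320, AT2G04037, AT5G28560, AT3G43833, AT2G10965 and AT4G05553, with 392 to 464 CHH calls there. Those named for lower columella were UNE4 (AT2G12940), AT3G42565, AT2G12935, AT4G07515, AT2G10553, AT4G07820, AT2G11815 and AT3G42310. The steepest of these was AT4G07515, with 260 calls in lower columella and 328 in columella root cap against 2 to 17 in the other sorted libraries (log2 change 5.00, SE 1.00, edgeR adjusted p = 0.00522 in lower columella). UNE4 had 286 and 353 against 6 to 32. Inside gene bodies, 383 of 2566 tested were called higher and 1 lower for CHH in columella root cap, and 81 higher and 1 lower in lower columella. Leaving out either endodermis line ended all flank and body calls of both populations, and leaving out either root tip raised the flank calls of columella root cap to 2779 and 2757 and its body calls to 1069 and 1053. Without either root tip the lower columella had 1355 and 1336 flanks called higher and 0 bodies (edgeR, 913 and 910 bodies at an unadjusted p under 0.05).

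**Figure D3:**
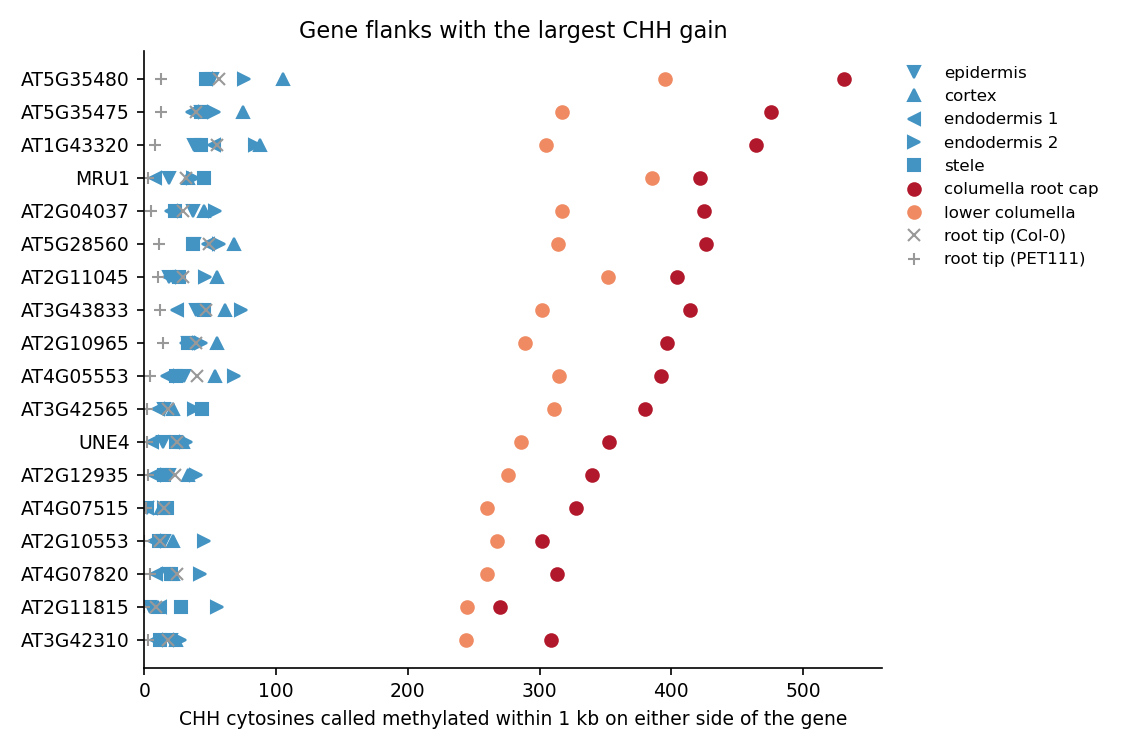
CHH cytosines called methylated within 1 kb on either side of the genes named by the fixed rule (x axis, number of cytosines), 1 mark per library. Columella root cap (270 to 531) and lower columella (244 to 395) lie apart from all other libraries in each gene.

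Of the 100 genes in the fixed lists, 31 had enough CHH calls to be tested in their flanks and 13 in their bodies. PXY (AT5G61480), a receptor kinase of the vascular meristem, was the only list member called higher in a columella population against the other tissues. Its body held 14 CHH calls in columella root cap, 1 in cortex and 0 in the 7 other libraries (edgeR adjusted p = 0.0196). The PXY body had too few depth-matched CHH sites to be tested with them. No flank of a list member was called in either columella population (edgeR; 3 and 2 flanks had an unadjusted p under 0.05). With depth-matched sites, 19 of 27 flanks were called higher in columella root cap and 14 in lower columella, and 6 and 8 of 10 bodies. Such calls were common over the whole genome: 26265 of 31023 CHH tiles were called higher in columella root cap and 16874 in lower columella. Depth-matched calls here and in the single lists below are therefore not particular to these genes. None of the members tested was called in CG or CHG in these 2 contrasts over all genes (edgeR; at most 3 genes per context and region had an unadjusted p under 0.05). Adjusted over the list alone, 1 epidermis gene body was called lower in CG in lower columella, COBL9, with 0 calls against 4 to 11 in the other sorted libraries (named after its values were seen). Against the root tips, the CHH bodies of SUVH2 and IBM1 were called higher in columella root cap.

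Genes of RNA-directed DNA methylation, the pathway that places CHH methylation at small RNA targets, had CHH calls in 6 flanks, of which 0 were called by edgeR over all genes or adjusted over the list alone in either columella population (1 flank had an unadjusted p under 0.05 in columella root cap and 0 in lower columella). With depth-matched sites, 6 were called higher in columella root cap and 4 in lower columella. DMS3 flanks held 164 and 147 calls in columella root cap and lower columella against 63 to 78 in the other sorted libraries, and SUVH9 flanks 149 and 112 against 21 to 58. Genes that maintain methylation had 5 testable flanks, none called over all genes or adjusted over the list alone (0 flanks had an unadjusted p under 0.05), and 2 called higher in each population with depth-matched sites. VIM3 flanks held 110 and 109 calls against 48 to 77, and VIM2 flanks 81 and 69 against 46 to 67.

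Among genes that remove methylation or hold it in check, IBM1, a histone demethylase gene with a methylated intron, had 118 and 101 CHH calls in its body in the columella populations against 11 to 34 in the other sorted libraries (log2 changes 2.52 and 2.24, edgeR adjusted p = 0.104 and 0.294). Depth-matched sites called it higher in both. The body of DME, a DNA glycosylase gene, held 16 CHH calls in endodermis line 1 and at most 1 in any other library. Adjusted over the list alone, 0 of these 3 bodies were called in either columella population, and each contrast had 1 with an unadjusted p under 0.05. Loci known to be controlled by methylation had 8 testable flanks and 6 bodies. None was called over all genes or adjusted over the list alone, 1 flank and 2 bodies had an unadjusted p under 0.05 in columella root cap and 1 body in lower columella, and with depth-matched sites 6 flanks were called higher in columella root cap and 4 in lower columella, and 4 and 5 of 5 bodies. QQS, an orphan gene of starch metabolism, had 267 and 170 calls in its flanks against 39 to 83, and HDG9 had 252 and 229 against 95 to 146.

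Few cell identity genes had enough CHH calls to be tested: no body or flank could be tested among 10 endodermis genes, 1 flank each among the epidermis, cortex and stem cell niche genes, 5 flanks and 3 bodies among the stele genes, and 4 flanks and 1 body among the columella genes. The flank of EGL3, an epidermal transcription factor, held 12 CHH calls in lower columella and 0 in the other 8 libraries (edgeR adjusted p = 0.228). It passed over the list alone, but as the only flank tested there its p was in effect unadjusted. The flanks of JKD held 105 and 124 calls in the columella populations against 55 to 101, and those of PLT2 held 137 and 145 against 100 to 147; neither was called over all genes or adjusted over the list alone. With depth-matched sites the PLT2 flanks were called higher in both populations (edgeR adjusted p = 0.0189 and 0.0261), and those of JKD in neither. In the list of columella identity, starch and gravity sensing, the body of ARL2, which acts in gravity signalling, held 368 calls in columella root cap and 285 in lower columella against 79 to 129 (log2 changes 1.84 and 1.42, edgeR adjusted p = 0.166 and 0.509). Over the list alone ARL2 passed in columella root cap, but as the only body tested there its p was in effect unadjusted. The flanks of BRN2, a root cap transcription factor, held 104 and 98 against 33 to 74 and were called in neither. With depth-matched sites the ARL2 body and the BRN2 flanks were called higher in both populations. Adjusted over the list alone, 1 of the 4 flanks of this list was called higher in lower columella and 0 in columella root cap. That flank was CYCD5;1, with 12 CHH calls in lower columella and 0 in the other 8 libraries, and CYCD5 drives the reporter of that line, so the call says little about columella genes. In the stele list, 1 of 3 bodies (PXY) was called in columella root cap over all genes and adjusted over the list alone, and 0 of 5 flanks in either population.

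Few CG changes were called, and these were local. HEI10 (AT1G53490), a gene of meiotic recombination, had 104 CG calls in its body in lower columella against 18 to 23 in the other sorted libraries and 19 in columella root cap, on chromosome 1 between 19963289 and 19966567 (log2 change 2.31, SE 0.06, edgeR adjusted p = 0.00357). It was also called higher in lower columella than in columella root cap (adjusted p = 0.0188). The gain was not confined to CG or to HEI10. The tile from 19963001 to 19964000, which also overlaps MRD1 and AT1G07887, held 78 CG, 54 CHG and 186 CHH calls in lower columella. No other library had more than 1 call there. AT4G11430 had 85 CG calls in lower columella, 37 in columella root cap and 15 to 29 in the other sorted libraries, but 48 and 40 in the root tips. AT5G47300 had 13 CG calls in its body in lower columella, against 75 to 82 in the other sorted libraries (log2 change -2.62, SE 0.13, adjusted p = 0.0249). Lower columella has 1 library, the only one of its line. For HEI10, AT4G11430 and AT5G47300, a state of the cell type and one inherited in the line therefore cannot be told apart. In columella root cap 1 body was called, AT2G07806, with 99 CG calls against 24 to 36 in the other sorted libraries and 26 and 24 in the root tips (log2 change 1.69, SE 0.07, adjusted p = 0.0435 against the other tissues, and 1.98, SE 0.09, adjusted p = 0.0498 against the root tips). Lower columella had 59 there, and the gene drops out of the test when regions above 3 times the median coverage are left out. Across 65419 CG tiles, lower columella had 2 called higher and 9 lower, and columella root cap 0 (1581 tiles at an unadjusted p under 0.05; limma called 1 higher and 3 lower). Against columella root cap, lower columella had 1 CG tile higher and 6 lower. Of 31937 CHG tiles, 2 were called lower in lower columella and 0 in columella root cap (833 tiles at an unadjusted p under 0.05; limma called 0). Leaving out any of the 4 replicates gave 118 to 187 CG tiles higher and 30 to 40 lower in columella root cap, and 149 to 177 higher and 72 to 93 lower in lower columella. With depth-matched sites none of the named CG bodies was called (edgeR adjusted p from 0.116 to 0.893), although the log2 changes kept their direction: 2.36 for HEI10, 4.95 for AT4G11430 and -4.58 for AT5G47300 in lower columella, and 1.40 for AT2G07806 in columella root cap.

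CG sites found in columella root cap and few other libraries were shared most with the root tip of the same line. Of 17749 CG sites listed in columella root cap and missing in 7 others, 38.0% were listed in the PET111 root tip. With any other library in its place the share was at most 10.7%, and with lower columella it was 9.57% of 12168. Missing sites told the line less clearly. Of 41013 CG sites missing in columella root cap and listed in 7 other libraries, leaving aside the PET111 root tip, 28.9% were also missing in that root tip, against 3.42% of the sites columella root cap does list. For lower columella as the second library the share was 4.72% of 30624 sites, against 1.31%. Some libraries of different lines shared missing sites as often: 29.3% of those of stele were missing in columella root cap (7.18% the other way), and 34.3% of those of epidermis in endodermis line 1 (43.1% the other way), the 2 libraries with the stricter CG calls. The most alike libraries were the endodermis lines, with 93.1% of the CG sites of either in both, and endodermis line 2 and stele shared 92.1%.

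**Figure D4:**
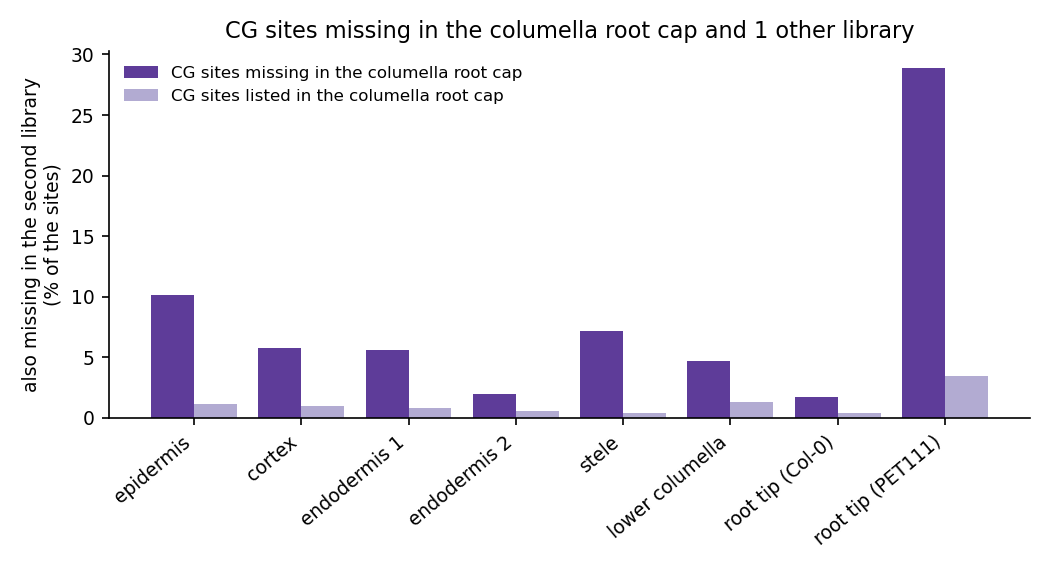
Share (y axis, percent) of CG sites missing in the columella root cap that were also missing in a second library (dark bars), beside the share missing there among sites the columella root cap does list (pale bars). The PET111 root tip, of the same line, stands at 28.9%, above lower columella at 4.72%.

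Few regions were called different between epidermis, cortex, endodermis and stele. The test had little power for CHH where it was simulated at the observed dispersion, the same in every tile, in the columella root cap contrast. There it recovered 2 of 100 CHH tiles changed 4-fold and 21 of 100 changed 8-fold. Power in the contrasts of these 4 tissues was not simulated. In CHH, edgeR called 0 tiles in epidermis, cortex and stele, with 100, 120 and 152 at an unadjusted p under 0.05, and 2 tiles lower in endodermis; limma called 25, 41, 35 and 70 tiles in epidermis, cortex, stele and endodermis. In CG, edgeR called 0 tiles in each of the 4 tissues, with 1231 to 1389 at an unadjusted p under 0.05, and limma called 10 lower in epidermis, 3 higher and 26 lower in cortex, 1 higher and 2 lower in endodermis, and 1 higher and 2 lower in stele. In CHG, edgeR called 0 tiles, with 191 to 460 at an unadjusted p under 0.05, and limma called 0. A few genes stood out. AT2G35460 had no CG call in its flanks in epidermis and 35 to 46 in all 8 other libraries (chromosome 2, calls from 14906738 to 14907495; edgeR adjusted p = 0.0141). AT1G20970 had 2 and 3 CG calls in its flanks in the endodermis lines and 26 to 31 elsewhere (log2 change -3.51, SE 0.15, adjusted p = 0.037), and with flanks of 500 bp its log2 change was 0.015. The body of AT2G27229 held 48 CHH calls in cortex and 0 in the other 8 libraries (chromosome 2, 11649060 to 11649629; adjusted p = 0.0173). Epidermis and cortex have 1 library each, from different lines, so tissue and line cannot be told apart for AT2G35460 and AT2G27229. The flanks of AT2G35460 were also called higher in endodermis (adjusted p = 0.037), against a mean that the empty epidermis lowers. No stele region was called in CG or CHH gene bodies or flanks (edgeR; 617 and 26 bodies and 432 and 45 flanks had an unadjusted p under 0.05; limma called 0 and 1 bodies, and 5 and 20 flanks). Without endodermis line 1 or line 2, however, 26 and 27 CG bodies were called higher and 3 and 3 lower in stele, and 21 and 23 CG flanks higher and 5 and 4 lower. Without either root tip 3 CHH flanks were called higher in stele. CG tiles called in stele went from 0 to between 25 and 142 higher and 3 to 7 lower as each replicate was left out, and in cortex to 66, 80 and 70 higher without endodermis line 1, endodermis line 2 and the Col-0 root tip.

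Columella root cap stood above whole root tips as well. In CHH, the median log2 change of tiles was 2.29, and edgeR called 2776 tiles higher and 0 lower (12119 at an unadjusted p under 0.05; limma called 6854 higher and 4 lower). The largest called gene bodies were AT2G10625, with 848 CHH calls against 117 and 36 in the Col-0 and PET111 root tips, AT1G35895, with 777 against 96 and 11, and AT3G32280, with 696 against 44 and 15. AT2G04037, MRU1 and AT2G11045 led the called flanks. The PET111 root tip, of the same line as the columella root cap but with 7 reads per site, had 0.301 times the called CHH sites of the Col-0 root tip and 0.828 times its depth-matched sites. Scaled by coverage of CHH instead of CG sites, the order turned, with 490585 depth-matched CHH sites in the PET111 and 369524 in the Col-0 root tip. The PET111 root tip also had the strictest CHH calls: at 20 reads its lowest number of methylated reads was 4, against 3 elsewhere. Without the Col-0 root tip 27723 tiles were called higher, and without the PET111 root tip, or without either endodermis line, 0 (edgeR, 18595, 1429 and 1333 at an unadjusted p under 0.05). Lower columella against root tip gave 0 called CHH tiles and 7593 at an unadjusted p under 0.05 by edgeR, with 97.9% of tiles higher.

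The endodermis lines and the root tips, treated as replicates, set the yardstick for these differences. Between the endodermis lines the log2 ratio of calls per tile had an SD of 0.29 in CG, 0.37 in CHG and 0.81 in CHH, and 8374 of 33718 CHH tiles differed over 2-fold. Between the root tips the CHH median was -1.67 with an SD of 0.94. These root tips differ in line and in median coverage (17 and 7 reads), so their gap is not the spread of like replicates. Over the whole library the PET111 root tip had 0.301 times the called CHH sites of the Col-0 root tip, but 0.828 times its depth-matched sites.

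The genes that drive the reporters were examined in their own lines. WOL (AT2G01830), the cytokinin receptor gene also known as AHK4, held 149 CHH calls in its body in stele, the WOL reporter line, against 15 to 50 in the other 8 libraries. Between positions 368751 and 369250 of chromosome 2, 124 cytosines were called in stele and 0 in any other library. Beside CYCD5;1 (AT4G37630), between positions 17678251 and 17679000 of chromosome 4, 17 cytosines were called in lower columella, 12 of them CHH, and 0 in any other library. At WER and AT1G09750, windows of 250 bp called in their own line alone held at most 2 calls, and SCR had no such window.

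**Figure D5:**
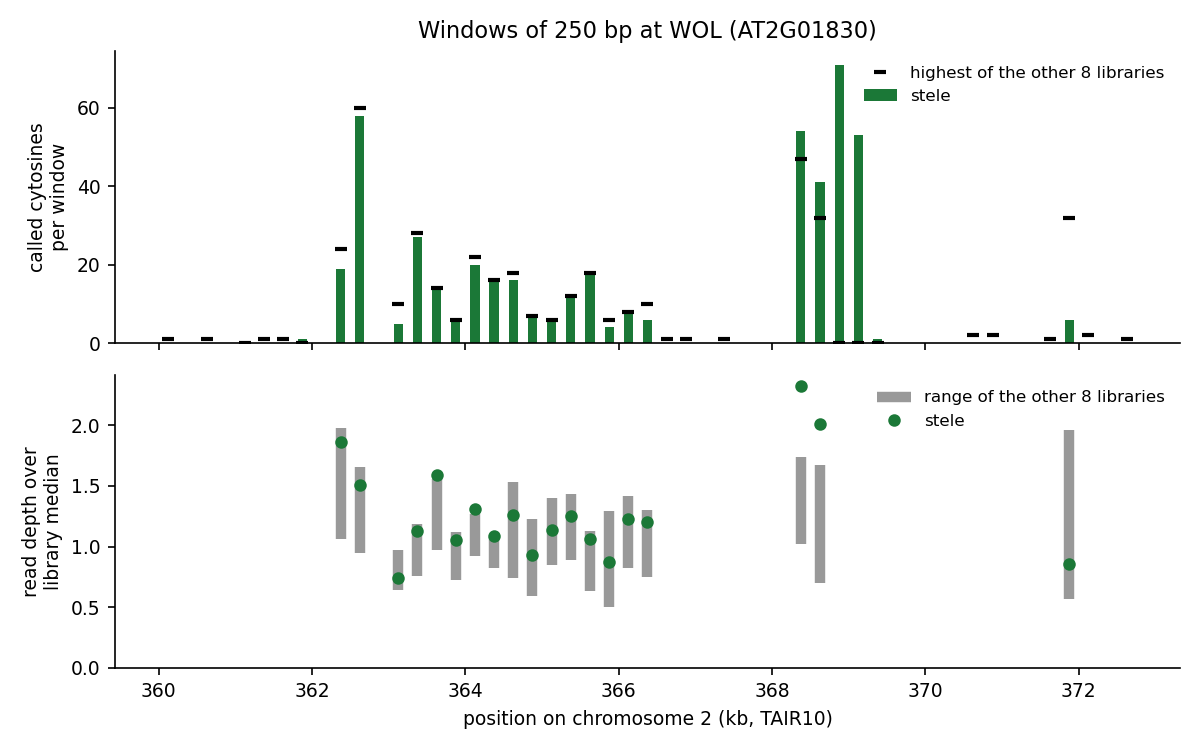
Called cytosines of all contexts (top, number per window of 250 bp) and read depth relative to the library median (bottom, sites listed in at least 8 libraries, windows with 3 or more such sites) along WOL on chromosome 2 (TAIR10, kb). Stele carries 124 calls in the 2 windows where the other 8 libraries have 0, and its depth in the windows beside them lies above the range of the others.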

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

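Both results were singled out, after they had been seen, because a signal appeared in read depth at the reporter genes, which no comparison of methylation used. At the 17 cytosines beside CYCD5;1 that were called in lower columella alone, read depth there was 5.49 times the library median, while the 9 tiles elsewhere with at least 40 calls in lower columella and at most 2 in any other library had 0.731 to 1.30 times. In WOL, at 60 sites between positions 368251 and 368750 of chromosome 2 listed in at least 8 libraries, depth in stele was 2.22 times the library median, against 0.927 to 1.70 in the other 8 libraries. At WOL sites between 365251 and 366500 the level was 53.2% in stele and 74.8% to 89.9% in the other libraries. This stretch was picked for its low level in stele and not for its depth. Depth there was 1.14 times the library median in stele, against 0.799 to 1.2 in the other libraries.

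The raised depths, and in the last stretch the low level, drew attention to the sites, so these values test no explanation for them. Extra copies of the driver sequence from the reporter transgene, methylation of the native genes in these cells and other sources of extra reads were not tested and all stay open.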

How the results depend on the processing

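Of 65 alternative values for the 6 library-level results, 62 kept their direction, and 3 of the called CG ratio (-0.006) turned positive: 0.008 with a minimum of 10 reads, and 0.011 and 0.011 with depth-matched sites by either coverage. Their exact permutation test cannot pass the threshold in this design, so its side says nothing about stability. Of 258 alternative counts of calls for 16 results, 111 stayed within 1.5 times and 147 moved; the cause was not tested except where stated. Of 909 alternative values for 64 named gene results, 644 kept their call, 226 lost it, 38 gained it and 1 reversed (AT1G20970 flanks in endodermis, 0.015 with 500 bp flanks). Counts below add higher and lower calls. CG and CHG counts and those of CG bodies and flanks are summed over 8 contrasts.

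Tile counts are given first. With 500 bp tiles CHH calls were 8788 in columella root cap, 3819 in lower columella, 0 in endodermis and 8823 for columella root cap against root tip, and CHG calls 0. With TMM factors CHH calls were 3847 in lower columella, 19 for lower columella against columella root cap, 1 in epidermis, 7 in endodermis and 3 in stele, CG calls 4 and CHG calls 40. With limma CHH calls were 562 for lower columella against columella root cap, 25 in epidermis, 41 in cortex, 70 in endodermis, 35 in stele and 6858 against root tip, CG calls 296 and CHG calls 14. With depth-matched sites CHH calls were 26274 in columella root cap, 16900 in lower columella, 0 in endodermis and 24300 against root tip, and with the Col-0 root tip only 19490, 6552, 0 and 13086; CG and CHG calls were 0 in both. Without epidermis and endodermis line 1, CHH calls were 0 in columella root cap, lower columella, endodermis and against root tip, CG calls 727 and CHG calls 430. With equal offsets CHH calls were 1964 in columella root cap, 439 in lower columella, 0 in endodermis and 0 against root tip, CG calls 2 and CHG calls 0. With root tip as reference, lower columella had 0 CHH calls. With a minimum of 1 read CG calls were 38 and CHG calls 0. With 5 reads CHH calls in lower columella were 1676, CG calls 0 and CHG calls 0. With 10 reads CHH calls were 576 in lower columella, 0 in endodermis and 0 against root tip, CG calls 0 and CHG calls 1.

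For bodies and flanks, CHH counts are given as columella root cap, then lower columella. TMM factors gave 252 and 220 bodies, 594 and 512 flanks, and 3 CG bodies. Depth-matched sites gave 1505 and 940 bodies, 5218 and 3721 flanks, 0 CG bodies and 0 CG flanks, and with the Col-0 root tip only 983 and 361 bodies, 3725 and 0 flanks, 0 CG bodies and 0 CG flanks. Without epidermis and endodermis line 1 there were 0 and 0 bodies, 0 and 0 flanks, 121 CG bodies and 245 CG flanks. Equal offsets gave 0 and 0 bodies, 66 and 0 flanks, 0 CG bodies and 0 CG flanks. Limma gave 149 bodies in lower columella, 682 and 429 flanks, 25 CG bodies and 81 CG flanks. With root tip as reference there were 12 bodies in lower columella, 59 and 0 flanks. Flanks of 500 bp gave 0 CG flanks. In lower columella a minimum of 1 read gave 17 flanks, 5 reads 135 bodies and 78 flanks, and 10 reads 0 bodies and 179 flanks. With 5 reads there were 1 CG body and 0 CG flanks, and with 10 reads 173 bodies in columella root cap, 0 CG bodies and 0 CG flanks.

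Leaving out each replicate in turn gave these ranges: called CG ratio -0.011 to -0.006, CG level 2.605 to 3.144, called CHG 0.088 to 0.109, CHG level 6.533 to 7.294, called CHH 1.195 to 1.302 and CHH level 15.045 to 16.411. CHH tiles ran from 0 to 18157 in columella root cap, 0 to 2502 in lower columella, 0 to 27723 against root tip, and 0 to 0 in the other 5 contrasts. CG tiles ran from 491 to 909 and CHG tiles from 2 to 628. CHH bodies ran from 0 to 1070 and 0 to 0, CHH flanks from 0 to 2783 and 0 to 1372, CG bodies from 4 to 159 and CG flanks from 0 to 299. These fits keep 1 residual degree of freedom, and a lone library is assumed to vary like the remaining pair. With so few, counts of called regions are weak evidence, and the direction and size of the CHH gain carry more weight.

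No paired analysis was possible because 5 of the 6 sorted populations have 1 library each, and the labels give the endodermis and root tip libraries no shared plants or batch. Not run were limma on log2((methylated + 1)/(unmethylated + 1)), levels over all covered sites and the correction for incomplete conversion, which need unmethylated or chloroplast cytosines, and the transposon contrasts, which need transposon annotation. Depth limits the PET111 root tip most, with a median of 7 reads per site, and its CHH calls had a stricter lower limit than those of any other library.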

Other observations

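By depth-matched sites, CCG sites were 18.1% of CWG sites (W is A or T) in columella root cap and 16.3% in lower columella, against 12.6% to 15.4% in the other sorted libraries, 12.7% in the Col-0 and 10.1% in the PET111 root tip (exact permutation p = 0.0952, the smallest possible). By called sites lower columella (192626 CCG and 765764 CWG) did not lie above stele (194448 and 764924), so the separation depends on depth matching. A few tiles were methylated in 1 library alone, with at least 40 calls there and at most 2 in any other: 9 in lower columella, 3 in cortex, 1 in stele and 1 in columella root cap. In lower columella the tile from 19963001 to 19964000 on chromosome 1, at MRD1 and HEI10, held 318 calls at a read depth of 0.864 times the library median. In cortex the tile from 11649001 to 11650000 on chromosome 2, at AT2G27229, held 123 calls. MRD1 and these tiles were chosen after their values were seen.

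The tests of the CHH gain were chosen only after the gain had been seen. Read depth alone does not account for it, since the log2 ratio of depth-matched CHH sites was 1.886. Incomplete bisulfite conversion alike across the genome does not account for the whole gain, since 0.274% of the extra calls of columella root cap, and 0.215% of those of lower columella, lay in tiles without calls in the Col-0 root tip, which were 28.4% of tiles. Calls in those tiles were also more numerous in the columella (8595 and 5616 against 2229 to 3735), so a small part from conversion stays open. The PET111 line does not account for the whole gain of columella root cap: the PET111 root tip had 0.8276 times the depth-matched CHH sites of the Col-0 root tip, or 490585 against 369524 when coverage of CHH sites was used for scaling, and 46.6% against 38.9% at shared sites, so a smaller part from the line stays open. CHH calls of the PET111 root tip had a stricter lower limit, and how far that changes its values was not computed. Tiles gained together in 2 lines with separate reference libraries (covariance 1.465), which a property of columella cells would give. With shared reference libraries the covariance was 1.504, against 0.058 in simulated unchanged libraries that share them. Those simulated libraries held no gain. A gain alike across the genome, whatever its source, was not simulated and could raise the covariance too, so the covariance does not decide. The line of lower columella has no other library and each population has 1 library, so sorting or culture differences stay open.

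The tests of CG sites peculiar to columella root cap were also chosen after the sites had been seen. Of the sites it lists and 7 others lack, 38.01% were listed in the PET111 root tip and at most 10.7% in any other library, the Col-0 root tip, which an inherited CG state of the PET111 line would account for. A shared tissue can come near that share, as the 2 endodermis lines had 32.4% and 25.3%. The sites it lacks do not decide: 28.86% were missing in the PET111 root tip too, but 29.3% of those of stele, of another line, were missing in columella root cap. A state common to both columella populations does not account for most of these missing sites, with 4.722% missing in lower columella. The PET111 root tip has the lowest coverage, so its own missing sites are in part unread ones.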
